A study of Mus musculus with 1000 samples.

How the data were processed

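Whole-brain RNA, with the cerebellum removed, was prepared for 3' RNA sequencing from 1000 third-generation mice descended from males treated with the chemical mutagen N-ethyl-N-nitrosourea (ENU), per the labels' protocols. ENU induces mostly single-base changes in the germ line, and inbreeding brings some of them to homozygosity in the third generation. The RNA of each mouse received an in-line index during cDNA synthesis, the cDNAs of 1 plate row were pooled, and each row pool was then made into a sequencing library with its own index combination, per the labels' protocols. The submitters' processing notes name the aligner GSNAP and the mouse genome build GRCm38, with no version of the aligner. The counting method and the gene annotation are not given in the sources used here.

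The 1 table used here was a list, as deposited by the authors, that pairs each library name with a text label (part1, part2 or part3) for the processed data file holding that library. It holds no read counts, no expression values and no quality measures. The expression files themselves were not analysed here. No gene, read depth, fold change or inflammation state could therefore be measured, the depth of every library is unknown, and no statistical test was run. The test planned for inflammation gene lists by pedigree was not run for this reason, and the gene lists and the rule for named genes fixed for it were not used. No genome coordinates were used.

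The list was joined to the samples by exact library name in pandas 2.3.3 under Python 3.11.15. Each library name was split into a pedigree code (the text before G3), an animal number (after G3), a well row and column, a number after the word neuro, and a number after the letter S. The labels do not define these fields. The pedigree code and animal number were read from the protocols' statement that third-generation siblings were screened, and the neuro number was taken as a plate and the S number as a row pool from the way they follow the well rows. A row pool was defined as 1 neuro number with 1 S number, and a full pedigree or row pool as one with 12 libraries in this series. Pedigrees were the groups, and siblings within a pedigree were numbered by the animal number, which does not pair animals of different pedigrees. The counting functions were tested on a small constructed layout with known answers. All results are counts over the whole series, so they carry no sampling error. Except where stated, the definitions and the alternatives to them were written before the data were examined. The library names had by then been read from the labels, and the pedigree, plate and row pool come from those names alone. An alternative count was called the same when it lay within 1.5 times the original. Pedigrees or row pools that were exceptions to a count were named where there were 5 or fewer. The 2 pedigrees with the fewest libraries, the pedigrees alone in partly filled rows and the plates named for their number of libraries fall outside that rule. They were chosen after their counts were seen. The 22231 list entries of other libraries were counted and not used further.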

Results

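The study sequenced RNA from the brains of many ENU-derived mice to find animals with abnormal inflammation states and, through exome sequencing, candidate causal variants. The part of the cohort described here comprised 1000 libraries from 1000 mice in 88 pedigrees, each library carrying a distinct combination of pedigree code and animal number. The mice were on a C57BL/6NCrl background, and the label that marks membership of a subset was FALSE for every library. No expression values were analysed here, so the results are limited to how the mice were distributed over pedigrees, plates, row pools and processed data files. Neither the inflammation state of any mouse nor the expression of any gene is reported.

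Of the 88 pedigrees, 80 were represented by 12 siblings. Another 6 pedigrees had 6 siblings each. ENU56330B6 had 3 siblings and ENU55108B6 had 1 mouse in this series. These last 2 pedigrees are named because of their small number of libraries in this series, a choice made after the counts were seen. ENU55108B6 therefore has no sibling here from which a spread within the pedigree could be estimated. The mouse of ENU55108B6 has animal number 9, and those of ENU56330B6 have numbers 10 to 12. Their counts in this series therefore need not be the sizes of these pedigrees. The list entries outside this series were not searched for further siblings of either pedigree.

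The first question that the design raises is whether a pedigree can be separated from the pool in which its libraries were made. The libraries fell into 87 row pools on 18 plates. In 87 of the 88 pedigrees all libraries came from 1 row pool, and 85 of the 87 row pools held 1 pedigree. These counts include 1 pedigree and 2 row pools with a single library, which meet them by construction. For 83 pedigrees, with 964 libraries, the correspondence was 1 to 1 in both directions within this series. For these pedigrees, a difference between pedigrees and a difference between row pools cannot be told apart from the layout of this series. Among them, ENU55108B6 (1 library), ENU56330B6 (3 libraries), and ENU55159B6 and ENU55433B6 (6 libraries each) lay in rows that this series filled only in part. Whether the remaining wells of those rows held other pedigrees was not examined, so their match may hold only within this series. The row pool was the unit of pooling, clean-up and library preparation in the protocol. This limit therefore holds for expression comparisons between those pedigrees that use only the libraries of this series. Siblings of a pedigree held in 1 row pool share that pool, so this limit does not apply to comparisons among them. Such siblings still differ in plate column.

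The 5 exceptions were the pedigrees that shared or crossed row pools. ENU56002B6 and ENU56169B6 each contributed 6 libraries to row H of plate neuro2136. ENU56064B6 and ENU56263B6 each contributed 6 libraries to row A of plate neuro2142. ENU55167B6 was the 1 pedigree split between pools, with 11 libraries in row C of plate neuro2075 and 1 library in row H of plate neuro2090. The first 2 cases allow a comparison of 2 pedigrees inside 1 pool, with 6 mice on each side. The 2 pedigrees still lie in different columns of the row, and the protocol ties the column to the in-line index. The split pedigree has siblings in 2 pools, but these pools are on different plates and a single mouse is in the second pool. A difference between these pools cannot be told apart from a difference between plates or between single mice.

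**Figure D1:**
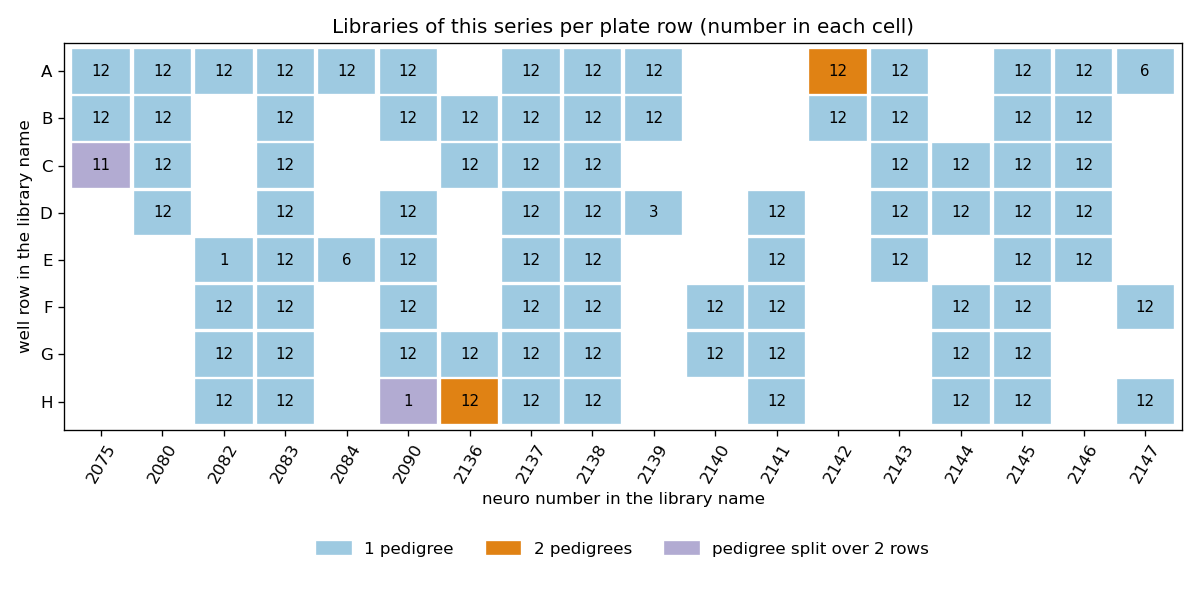
Libraries of this series in each plate row, with the neuro number (taken as the plate) on the horizontal axis and the well row on the vertical axis; the number in each cell is the count of libraries and empty positions hold none of this series. Of 87 occupied rows, 85 hold 1 pedigree, the 2 orange rows hold 2 pedigrees of 6 libraries each, and the purple rows mark the pedigree split into 11 libraries and 1 library.

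The second question is whether pedigrees can be compared within a plate. Each of the 18 plates held at least 2 pedigrees of this series, and the number of pedigrees per plate ranged from 2 to 8. Plates contributed between 18 and 96 libraries, with a median of 54.5, and 4 plates (neuro2083, neuro2137, neuro2138 and neuro2145) contributed 96 libraries each. Pedigrees can therefore be set side by side on every plate, but only on neuro2136 and neuro2142 did any of them share a row pool. On every other plate, each pedigree of this series occupied a different row pool. Within those plates, a difference between pedigrees and a difference between row pools cannot be told apart.

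The third question is whether the division of the processed data into files adds a further split. All 1000 libraries were matched by exact name to 1 entry each in the list of 23231 libraries, of which they made up 4.3%. The list divides the libraries over 3 parts of 7743, 7743 and 7745 entries. All 1000 libraries of this series were assigned to the third part. As far as this series represents them, all 88 pedigrees and all 18 plates therefore lay within 1 processed file. The parts that hold other libraries of these pedigrees or plates were not examined. No comparison among these mice would cross a boundary between files.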

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

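The count of row pools holding 1 pedigree depended on how a pool was defined. It was 85 of 87 by plate and S number together, 79 of 81 among full row pools, and 51 of 70 by the S number alone, because 17 S numbers occurred on 2 plates each. By the plate alone, a definition added after the data were seen, it was 0 of 18, since each plate held at least 2 pedigrees. The S number alone and the plate alone merge separate row pools. Neither could have raised this count, so neither tests its stability. The count of pedigrees held in 1 row pool was 87 of 88, and 79 of 80 among full pedigrees. It was also 87 by the S number alone and by the plate alone, but these definitions only merge row pools and could not have lowered it, so they say nothing about its stability. Restriction to full pedigrees left 960 libraries and 80 pedigrees in the third part, which was fixed in advance because all 1000 libraries lie there. Matching names without the read suffix again found 1000 libraries. No paired analysis was possible because the list holds no expression values and animal numbers do not pair mice of different pedigrees. The alternatives planned for expression data (the replicate block, another normalization and no filter on low counts) were not run for the same reason, and leaving out single mice was not run because no pedigree mean was computed. Depth is unknown for every library.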

Other observations

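The following counts were chosen after the library names had been seen, and no explanation for them was tested. The S number matched the well row for all 1000 libraries, when S numbers are counted in blocks of 8 from row A to row H, and each of the 18 plates lay within 1 such block. The plates neuro2136 to neuro2147 occupied block positions 1 to 12 in order, with 681 libraries from 60 pedigrees. Of the other plates, 5 between neuro2080 and neuro2090 followed 1 common numbering in the same way, with 284 libraries from 26 pedigrees. Plate neuro2075, at block position 10 with 35 libraries from 3 pedigrees, did not follow that numbering. It holds 11 of the 12 libraries of ENU55167B6, whose remaining library is on plate neuro2090. No pedigree had libraries both on plates neuro2136 to neuro2147 and on the other plates. The labels do not say which plates were sequenced together.

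Within rows, the order of the animals was often fixed as well. In 41 of the 79 full pedigrees that lay in 1 row pool, animal numbers increased across the columns without exception. In those 41 pedigrees the rank of the animal number and the plate column, which the protocol ties to the in-line index, coincide.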
